A study of Mus musculus with 2 samples.

How the data were processed

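H3K4me1 was profiled by ChIP-seq in 2 biological replicates of mouse midbrain at embryonic day 10.5, each a pool of male and female embryos (69 and 51), with fragments of 300 to 500 bp per the labels. The reads were processed by the authors, and 4 peak lists on the mouse assembly mm10 (per the labels) were the starting point here. Per the text files deposited with the lists, the list of each replicate was made from the alignments of that replicate, the joint list from the alignments of both, and the replicated list from the joint list and both replicate lists. The same files name 2 further input files as parents of the lists of replicate 1 and of the joint list, but 1 for the list of replicate 2. What these inputs hold is not stated there, although the labels name a possible control experiment. The peak caller, its threshold, the aligner and the rule for a replicated peak were not given in the sources used here. The smallest -log10 p was just above 2 in each list.

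Each peak has a signal value, which the authors deposited as a linear ratio (fold over a background that is not stated), and a -log10 p-value and -log10 q-value that are also the authors'. The signal was used only to rank or describe peaks within a list, and the -log10 q only to filter. Peak lists hold no read counts, so the depth per sample is unknown and no interval from counting error can be given. All 146616 replicated peaks were identical to joint peaks, and 99559 of them (67.9%) had at least 50% of their length in each replicate. Only 1 joint peak that met this condition was not in the replicated list.

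Chromosomes 1 to 19 and X were analysed. The sequence was GRCm38.p6 and the annotation GENCODE vM21, both of the same assembly as mm10, and all peak ends lay within the chromosome lengths. Genes were the 21728 protein-coding genes of the annotation, with the 5' end of the gene as TSS and, for repeated symbols, the longest gene. Coordinates are 1-based. Cover of a gene is the percent of the bases within 50 kb of its TSS that lie in merged peaks. A TSS was CpG-rich when the sequence within 500 bp had a CpG observed to expected ratio of at least 0.6 and a GC content of at least 50%. TSS profiles used 100 bp bins to 5 kb on each side, with the centre within 100 bp and the flanks from 1 to 2 kb.

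The median cover of 20 gene lists and 3 symbol families, fixed before the data were examined, was given as a percentile among 10000 random lists of the same size matched on gene length (10 classes) and the number of TSSs in the window (3 classes). A list was called high or low only if the replicated list and both replicates fell above or below the central 95% of the random lists. These percentiles describe the 2 libraries, and genes are not replicates. The midbrain list was compared with each other list by a two-sided permutation test over genes (100000 resamples, Benjamini-Hochberg adjustment over 19 lists), leaving shared genes out of the other list. Genes were not matched on any property in this test. For the difference between replicates the log2 ratio of cover plus 1 percentage point was centred on the median of all genes. The design has 1 group, so no test between conditions was possible.

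Peaks of the replicates counted as shared when at least 50% of the length was covered by the other list. Chance overlap and the annotation of midpoints came from 100 circular shifts within chromosomes that left the unsequenced first 3 Mb out. Motif matches on both strands were counted in replicated peaks over 2 kb from any TSS and in flanks of the same width 5 kb outside, leaving out flanks that touch a joint peak. Percentile intervals came from 1000 bootstrap resamples of 5 Mb blocks, and the reversed, not complemented, motif served as a control for base content, though not for CpG content where reversing makes or removes a CpG. All steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.

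The rule for named genes, fixed before the data were examined, took the 6 highest and 2 lowest members of the midbrain list, the highest and lowest member of each other list, and the 10 genes with the highest cover of all, 1 per window. It also took the 5 strongest peaks, the 5 longest domains of peaks merged within 1 kb, and the 5 genes with the largest ratio between replicates in each direction among genes with at least 10% cover in a replicate. Genes outside this rule are said to be chosen after their values were seen.

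The overlap and list steps were tested on simulated data. With 69.9% of 146616 peaks left in place, 70.5% were found shared. Of 100 unchanged lists of 20 genes drawn from the 21728 genes 7.0% were called, and of 20 lists with cover added at each TSS, 4 were called high with 3 kb added and 20 with 6 kb. These simulated calls rested on 1 list of shifted peaks, while the calls on the data also required both replicates. Alternatives covered a -log10 q of at least 2, equal peak numbers, other overlaps, the joint list, each replicate alone, other promoter and window widths, other TSS sets, unmatched lists, means, a pseudocount of 5, other motif flanks and distances, and, added after the data were examined, 5 further settings. These were replicated peaks with at least 50% of their length in each replicate, 1 member per cluster of windows, matching on GC content in 5 classes with the CpG class (and coarser classes, 3 of gene length and 2 of gene density), matching on these coarser classes alone, and the part of each window nearest to the gene's own TSS. The 4 joint peaks on other sequences were left out of all comparisons.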

Results

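Monomethylation of lysine 4 of histone H3 (H3K4me1), a chromatin mark known to lie at enhancers and beside active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos of the strain B6NCrl at embryonic day 10.5. The labels give 1 group of 2 biological replicates, pools of male and female midbrains from 69 embryos in replicate 1 and 51 embryos in replicate 2, and no other tissue, stage or treatment. The comparisons are therefore between genes, regions and the replicates of this group. The deposited peak lists carry no read counts, so the sequencing depth of each replicate is unknown. On the 19 autosomes and the X chromosome the list of replicate 1 held 216981 peaks that covered 140 Mb, and the list of replicate 2 held 159471 peaks that covered 120 Mb (mean 130 ± 14.7 Mb, SD, n = 2). The authors' replicated list, used below unless stated otherwise, held 146616 peaks with a median width of 665 bp and covered 145 Mb, 5.67% of the sequenced bases. Values written with ± are the mean and SD of the 2 replicates.

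Genes of the midbrain and of the isthmus, the organising tissue at its border with the hindbrain, were densely covered by H3K4me1 peaks. Of the 20 members of this list, 18 had more than 13.8% of the window within 50 kb of the transcription start site (TSS) under peaks, which is the upper quartile of 21728 protein-coding genes, and 0 members lay below the median of all genes of 6.58%. The median of the list was 26.3% in the replicated list and 23.5 ± 0.65% over the replicates, above each of the 10000 random lists matched on gene length and local gene density, whose central 95% of medians spanned 1.85% to 9.16%. The highest member was Dmbx1, a homeobox gene of the early midbrain on chromosome 4 (115915119 to 115939926, mm10), with 55.9% of its window covered (50.9 ± 4.94%). Pax7 and Pax3, paired box genes of the dorsal neural tube, had 53.6% and 48.2% (49.5 ± 2.36% and 42.6 ± 4.67%). Lmx1b, which acts in the isthmus and in dopaminergic progenitors, had 51.0%, and En2 and Pax5, both expressed at the midbrain-hindbrain border, reached 45.6% and 31.2%. The lowest members were Pou4f1, a gene of postmitotic neurons, with 7.27%, and Nkx6-1, a gene of the ventral neural tube, with 12.5%.

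**Figure D1:**
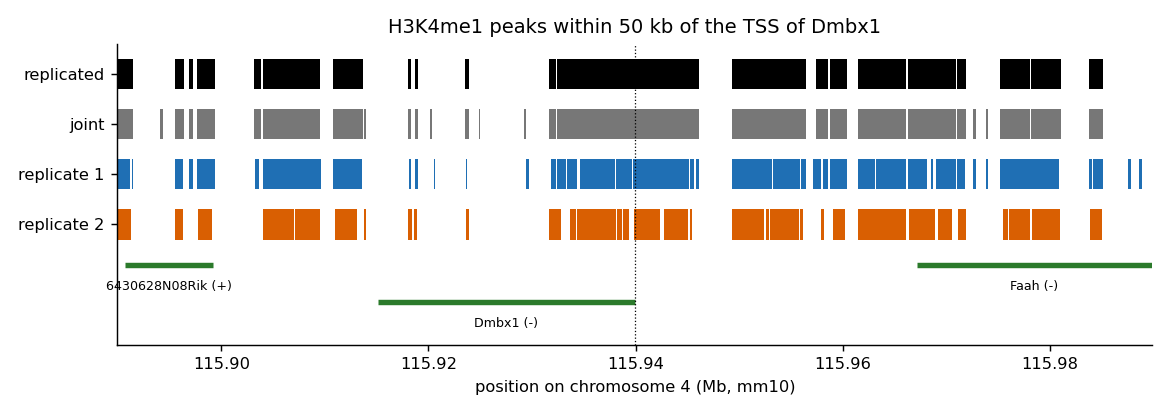
H3K4me1 peaks of the replicated list, the joint list and both replicates (coloured blocks, 1 row per list) within 50 kb of the TSS of Dmbx1, against the position on chromosome 4 in Mb (mm10), with protein-coding genes and their strands as green bars and the TSS as a dotted line. Peaks of the replicated list cover 55.9% of the window, those of replicate 1 cover 54.3% and those of replicate 2 cover 47.4%.

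Progenitor and signalling genes were covered as densely as the midbrain genes. The neural progenitor list had a median of 28.9% (26.2 ± 1.68%), led by the receptor gene Notch1 with 53.5%, and 18 of its 20 members lay above the upper quartile of all genes. Its lowest member was the X-linked gene Sox3 with 7.13%. The list of signalling genes had a median of 25.8% (23.5 ± 1.78%), from 11.2% at Shh, the ventral signal Sonic hedgehog, to 45.3% at Lfng, a modifier of Notch receptors. Genes of neurogenesis had a median of 17.5% (15.5 ± 1.94%). In that list the proneural gene Neurog1 had 42.6% and Stmn2, a gene of differentiating neurons, had 2.93%. The forebrain list had a median of 13.0% (12.4% and 11.7% in the replicates), from 3.42% at the X-linked gene Arx to 24.5% at Emx1. These lists lay above the central 95% of matched random lists in the replicated list and in both replicates.

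Lists of tissues outside the neural tube had lower medians than the midbrain, progenitor and signalling lists, and the calls for 4 of them depended on the settings. The list of cranial mesenchyme and neural crest had a median of 11.8% (10.1 ± 0.07%), from 0.353% at the collagen gene Col3a1 to 36.1% at Prrx2, and was called high. Microglia and myeloid genes (median 14.0%), surface epithelium genes (13.1%) and skeletal muscle genes (11.95%) were also called high. Their extremes were 38.5% at C1qb and 0% at Itgam, 27.8% at Cldn7 and 1.14% at Trp63, and 37.6% at Tnnt3 and 0.68% at Ttn. With random lists matched also on the GC content of the window and the CpG class of the TSS, a comparison added after the data were examined, the percentiles were 68.9 for microglia and myeloid genes, 72.6 for surface epithelium and 48.3 for skeletal muscle. These 3 lists and cranial mesenchyme also lost the call with unmatched random lists. Microglia and surface epithelium genes lost it with windows of 10 kb and 100 kb and with 1 member per cluster of windows (87.1th and 96.2th percentile), microglia genes also with a -log10 q of at least 2, and surface epithelium genes also with means. Skeletal muscle lost it with windows of 10 kb and means, and cranial mesenchyme with windows of 100 kb and means. Under that matching the list of cranial mesenchyme stayed at the 98.6th percentile in the replicated list but no longer passed in both replicates, and the midbrain, progenitor, neurogenesis, forebrain and signalling lists kept their calls.

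Genes of dopaminergic neurons, which are born in the ventral midbrain, had a median of only 7.45% (7.10 ± 1.27%), at the 83.8th percentile of matched lists. Ddc, an enzyme of dopamine synthesis, had 27.3% and Gch1, an enzyme of its cofactor, had 1.26%. The hindbrain list had a median of 12.6% (10.8 ± 0.79%), led by Gbx2, which is expressed on the hindbrain side of the isthmus, with 30.9%, and ending with Phox2b at 7.13%. It was not called, with percentiles of 92.0 in replicate 1 and 97.95 in replicate 2. It was called high with windows of 10 kb (99.7th percentile) and lay at the 20.4th percentile with matching on GC content and CpG class, where random lists had a median of 14.4%. The posterior Hox list, 19 genes in 5 clusters of windows, had a median of 8.91%, from 2.92% at Hoxb13 to 16.1% at Hoxd8. It lay at the 41.9th percentile of lists matched on length and density and was called low, at the 0.01th percentile, once GC content and CpG class were matched, where random lists had a median of 17.8%.

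Further lists without a call were those of glia (median 15.0%, Mbp 31.7% and the X-linked gene Plp1 4.39%), synapses of mature neurons (12.2%, Camk2a 43.8% and Gabra1 1.64%), endothelium (11.4%, Nos3 39.6% and Emcn 1.26%) and housekeeping genes (13.4%, Rplp0 29.6% and the X-linked gene Hprt 0.901%). The same held for cardiac genes (8.45%, Myl3 23.1% and Smyd1 0.96%), germline and pluripotency genes (7.39%, Mael 22.1% and Dppa4 0%) and erythroid genes (6.03%, Nfe2 28.2% and the X-linked gene Alas2 0%). Some of these lists were called high under alternatives: housekeeping genes with windows of 10 kb and 100 kb, unmatched random lists and replicate 1 alone, synapse genes with windows of 100 kb, means and 1 member per cluster, and glia genes with replicate 1 alone and coarser matching classes. Percentiles in the replicated list were 99.2 for glia, 97.61 for housekeeping, 97.43 for synapse and 96.8 for endothelial genes. Glia and housekeeping genes missed the call only in replicate 2 (97.37th and 96.2th percentile). With matching on GC content and CpG class the replicated list gave 98.3 for glia, 95.55 for housekeeping, 85.4 for synapse and 86.0 for endothelial genes. Liver genes had the lowest median of the 20 lists, 4.46%, with Apoa2 at 27.7% and Serpina1a at 0%, and were called low, at the 2.01th percentile, only when GC content was matched. Among the families taken by symbol, 1173 of 1462 chemosensory receptor genes and 19 of 57 keratin-associated genes had no peak in the window, and both families were called low. The keratin-associated family lost its call with GC matching (96.2th percentile), as did the chemosensory receptors, for which 47.1% of the genes in the GC-matched random lists were members of the family itself. The histone family, in which 34 of 132 symbols start with H2- and belong to the major histocompatibility complex, had a median of 13.0% and was called high. That call was lost when 1 member per cluster of windows was kept (86.1th percentile).

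**Figure D2:**
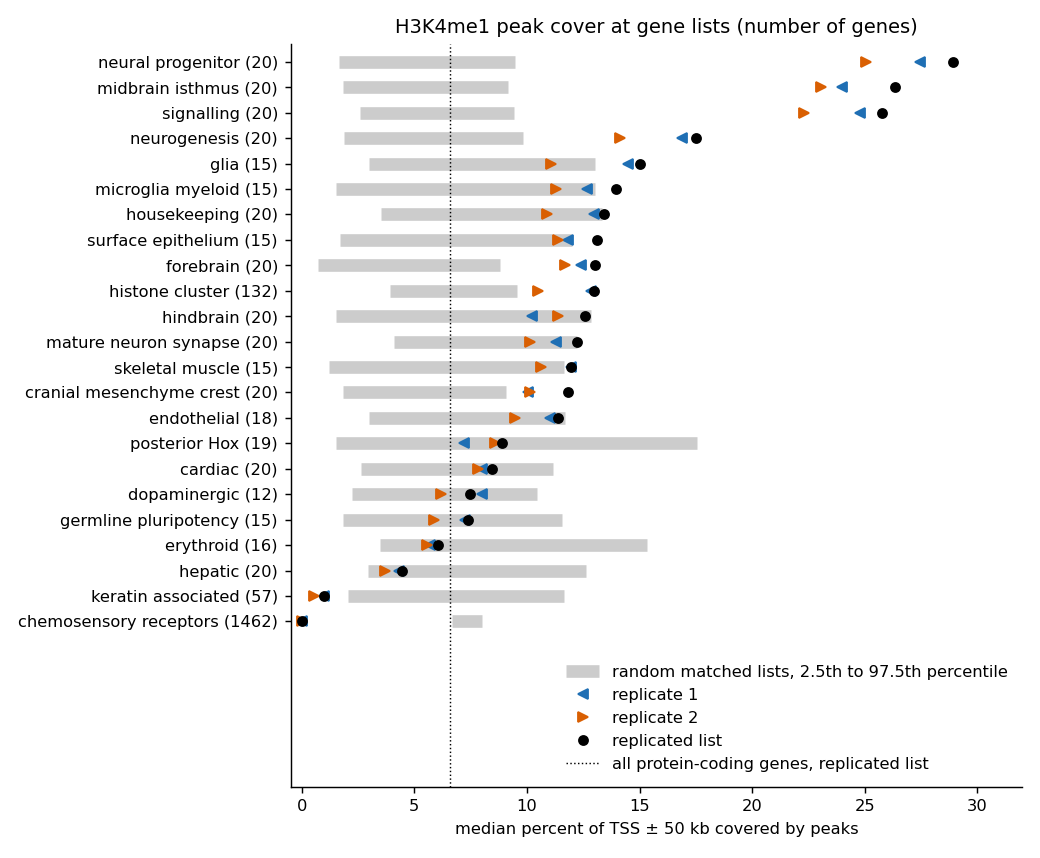
Median percent of the window within 50 kb of the TSS that lies under H3K4me1 peaks, for 20 gene lists and 3 families (rows, number of genes in brackets). Circles are the replicated list, triangles the 2 replicates, grey bars the central 95% of 10000 random lists matched on gene length and gene density, and the dotted line is the median of all protein-coding genes, 6.58%; neural progenitor genes (28.9%), midbrain genes (26.3%) and signalling genes (25.8%) lie farthest above their bars.

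Set against the other 19 lists directly, the midbrain list had the higher median in 18. The difference was largest to liver genes, 21.9 percentage points, and was seen in both replicates (19.5 ± 0.23, adjusted permutation p = 9.5e-05). It was 20.3 points to erythroid genes (raw permutation p = 1e-05, the smallest that the resamples allow), 18.9 to dopaminergic genes (adjusted permutation p = 0.00021), 17.4 to posterior Hox genes, 13.8 to hindbrain genes (adjusted permutation p = 0.0014) and 13.3 to forebrain genes (11.5 ± 0.17, adjusted permutation p = 9.5e-05). In total 17 of the 19 differences had an adjusted permutation p under 0.05, all with the midbrain list higher. The exceptions were signalling genes, with a difference of 0.586 points that changed sign between the replicates (adjusted permutation p = 0.88), and neural progenitor genes, whose median was 2.56 points higher than that of the midbrain list (adjusted permutation p = 0.50). The tests were two-sided permutation tests over genes with Benjamini-Hochberg adjustment over the 19 lists, and genes are not independent replicates. They did not match the lists on gene length, gene density, GC content or CpG class. The GC content of the windows and the share of CpG-rich TSSs differed between the lists. How much of each difference to the midbrain list comes from such properties was not tested. The difference to neurogenesis genes, 8.82 points (adjusted permutation p = 0.014), no longer passed in the list of replicate 1 alone (7.09 points, adjusted permutation p = 0.065; from 0.0028 to 0.015 in the other alternatives). With windows of 100 kb the differences to microglia and myeloid genes (8.64 points, adjusted permutation p = 0.10; from 0.00065 to 0.037 in the other alternatives) and to housekeeping genes (5.53 points, adjusted permutation p = 0.14; from 3.8e-05 to 0.0026 in the others) did not pass either.

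Over all protein-coding genes the densest windows belonged to Flrt1, a gene of a neuronal transmembrane protein on chromosome 19 (7092001 to 7105729), with 78.2% (71.9 ± 4.24%), and Efna2, an ephrin gene on chromosome 10 (80179482 to 80190010), with 75.3% (69.5 ± 4.63%). Ccdc85c (71.9%), the ephrin receptor gene Ephb2 (68.8%), Tcf20 (63.5%), Igdcc3 (62.8%), the corepressor gene Ncor2 (62.3%), Gnat1 (59.9%), Dohh (59.9%) and Gins2 (58.4%) followed. The window of Gins2 reached into the neighbouring gene Gse1, which held the strongest peak and the longest domain. That peak lay in an intron of Gse1 (chromosome 8, 120544505 to 120567163, mm10), was 22659 bp long and had a signal of 19.22, the authors' fold value for the peak. The second peak by signal, 17.3, lay in the same gene, and the next lay in introns of Foxp4 (chromosome 17, 47902734 to 47911990, signal 17.2), Ahdc1 (chromosome 4, 133041043 to 133053458, signal 16.5) and Gnai2 (chromosome 9, 107623970 to 107634565, signal 16.3). Peaks merged within 1 kb formed 97628 domains, of which 980 were 10 kb or longer. The longest spanned 96323 bp of Gse1 (120481166 to 120577488), with 92.3% of its bases under peaks of replicate 1 and 91.8% under peaks of replicate 2. It was followed by domains of 72625 bp over Ccdc85c, 63381 bp in Msi2, a gene of a neural RNA-binding protein, 62612 bp in Gse1 and 59060 bp over Efna2 and its neighbours.

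Most peaks lay away from TSSs. Of the peak midpoints 47.8% fell in introns (48.7 ± 1.19%), 37.2% between genes (36.9 ± 0.31%), 9.28% within 1 kb of the TSS of a protein-coding gene (8.76 ± 1.26%) and 5.66% in exons (5.69 ± 0.24%). In 100 circular shifts of the list within each chromosome the shares averaged 37.0% in introns, 57.8% between genes and 1.67% near TSSs, so that promoter positions were 5.55-fold and intron positions 1.29-fold more frequent than in the shifted lists. The median distance to the nearest protein-coding TSS was 34.2 kb, and 26.0% of the peaks were more than 100 kb away. The promoter share rested on its definition, with 4.45% within 500 bp, 16.8% within 2.5 kb and 18.5% within 1 kb of any annotated transcript start.

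The distribution around TSSs differed between promoter classes. At the 9729 CpG-rich TSSs the mark flanked the start, with 46.7% of genes covered 1 to 2 kb away (42.5 ± 2.98%) and 31.2% covered within 100 bp (25.5 ± 3.26%). The downstream side was covered more than the upstream side, 64.4% against 28.9%, with a maximum of 75.3% at 1050 bp downstream. At 1 to 2 kb the upstream side lay below the centre in the replicated list and in replicate 2, but not in replicate 1. Nearer to the TSS the upstream cover reached 58.9% at 550 bp. At the 11999 CpG-poor TSSs the order was turned, with 27.6% covered within 100 bp (25.1 ± 0.11%) and 13.4% in the flanks (12.5% and 11.4% in the replicates). The difference of flank minus centre was 15.5 percentage points at CpG-rich TSSs (17.0 ± 6.24) and -14.2 at CpG-poor TSSs (-13.1 ± 0.90), and each was larger than the spread between the replicates. Over all genes together the difference was -0.885 points and changed sign between replicate 1 (2.69) and replicate 2 (-1.96). At CpG-rich TSSs without another TSS within 10 kb it was 7.46 points.

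**Figure D3:**
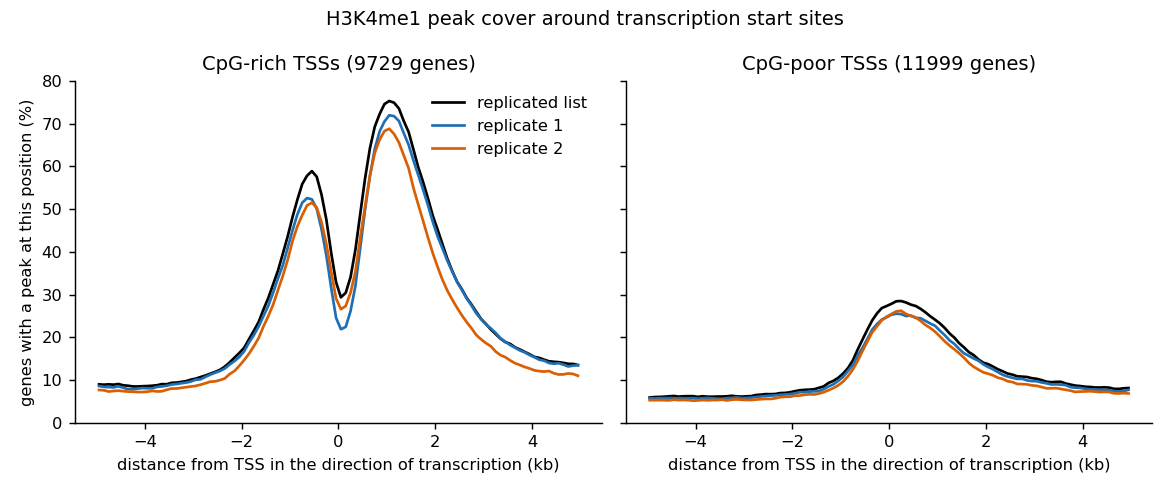
Percent of genes with an H3K4me1 peak in 100 bp bins from 5 kb upstream to 5 kb downstream of the TSS, for CpG-rich TSSs (left, 9729 genes) and CpG-poor TSSs (right, 11999 genes). Lines are the replicated list and the 2 replicates; cover peaks at 75.3% at 1050 bp downstream of CpG-rich TSSs, with a dip at the TSS, and at 28.5% just downstream of CpG-poor TSSs.

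Several sequence motifs, among them the proneural E-box, RFX, SOX and POU motifs, were more frequent in distal peaks than in the flanking sequence. The 103008 replicated peaks more than 2 kb from any TSS had a GC content of 48.6% against 43.8% in 143754 flanks, so each motif was set against its reversed form. The proneural E-box CAGMTG, bound by basic helix-loop-helix factors, had 2.53 matches per kb in peaks and 1.77 matches per kb in flanks, a ratio of 1.43 (95% interval 1.41 to 1.44 from 1000 bootstrap resamples of 5 Mb blocks), while its reversed form had a ratio of 0.730. The E-box CAGCTG, which reads the same on both strands, was counted on each of them and so 2 times per site. The same held for GTCGAC, the reversed form that holds a CpG. The RFX motif had a ratio of 1.88 (1.82 to 1.95) against 1.203 for its reversed form, the SOX motif 1.23 (1.22 to 1.25) against 0.982, the POU motif 1.16 (1.12 to 1.19) against 0.692 and the TEAD motif 1.12 (1.10 to 1.14) against 0.853. The excess over the reversed form had an interval above 0 for 10 of 13 motifs and below 0 for none of them. The reversed forms of the POU, RFX, CTCF and NFI motifs and of 1 of the 2 E-boxes hold a fixed CpG that the motif lacks. The RFX and NFI motifs can hold a CpG only where a base is left open. The ETS motif holds a CpG that its reversed form lacks. For all these motifs the excess is not free of CpG content. For POU most of the log2 excess of 0.74 came from the fall of the reversed form (-0.53) and not from the motif (0.21). The log2 excess was 0.39 for TEAD, 0.33 for SOX and 0.25 for MEF2. It was 0.16 for the homeodomain core and for GATA, 0.07 for AP-1 and 0.06 for OTX, the motif class of the midbrain factor Otx2. The homeodomain core (ratio 0.791), the GATA motif (0.821) and the MEF2 motif (0.895) were less frequent in peaks than in flanks but less depleted than their reversed forms. For HNF4 (0.17), ETS (0.21) and CTCF (0.37) the interval of the log2 excess included 0, for CTCF a wide one (-0.46 to 1.21). The CTCF motif itself had a ratio of 1.89 (1.69 to 2.12) against 1.47 for its reversed form. The ETS motif had 1.34 (1.13 to 1.61) against 1.16. The NFI motif, with 86 matches in peaks, was too rare for an interval. The OTX excess was 0.02 (-0.03 to 0.06) in the list of replicate 2 alone, and the MEF2 excess was 0.15 (-0.03 to 0.32) in peaks over 10 kb from a TSS. The HNF4 excess lay above 0 in each replicate alone (0.25 and 0.33) and in the joint list, and the ETS excess with flanks 20 kb away (0.28).

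Both replicates marked largely the same strong regions. Of the peaks of replicate 1, 55.0% had at least 50% of their length under peaks of replicate 2, against 4.83 ± 0.17% (mean and SD of 100 shifted lists), and 76.5% of the peaks of replicate 2 were found in replicate 1, against 5.59 ± 0.21% in shifted lists. Of the bases covered in either replicate 61.6% were covered in both. In the strongest 10% by signal 99.5% of the peaks of replicate 1 and 99.9% of those of replicate 2 were shared, and in the weakest 10% the shares were 22.1% and 53.9%. Replicate 1 had 1.36 times as many peaks as replicate 2, with a median width of 357 bp against 469 bp, and covered 1.17 times the length. The authors' replicated list held 146616 of the 218858 joint peaks on these chromosomes, from 19.0% of the weakest 10% by signal to 100% of the strongest 10%. Of the replicated peaks 30288 (20.7%) touched no peak of at least 1 replicate, and their median signal was 2.65 against 3.81 for the others.

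**Figure D4:**
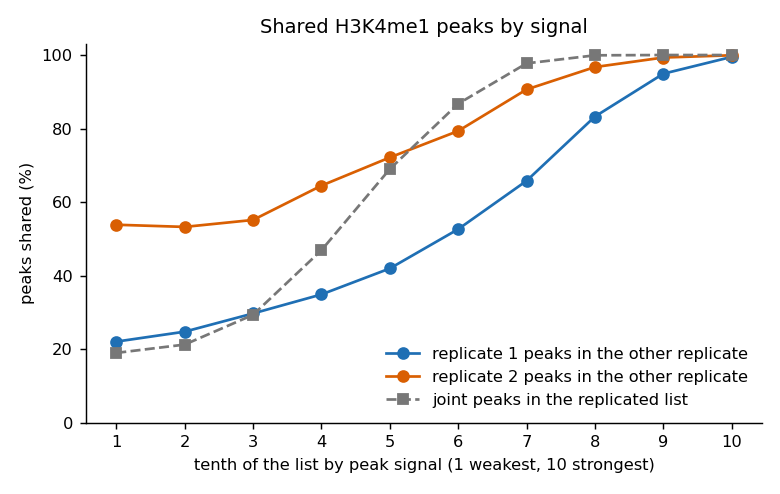
Percent of peaks shared, in 10 equal parts of the list ranked by the authors' signal value within that list. Circles give the peaks of each replicate with at least 50% of their length in the other replicate, and squares the joint peaks kept in the replicated list; the share rises from 22.1% to 99.5% for replicate 1 and from 53.9% to 99.9% for replicate 2.

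The replicates differed in the relative cover of some gene lists, a comparison of 1 library with 1 library that has no replicate check. Relative to all genes, whose median log2 ratio of replicate 1 to replicate 2 was 0.10, the lists of posterior Hox genes (-0.20), cranial mesenchyme (-0.15), hindbrain (-0.12) and forebrain (-0.12) were covered more in replicate 2. The hindbrain value was carried by its 10 Hox members (-0.29), which lie in clusters that also hold posterior Hox genes, while its 10 other members showed no such shift (0.03, 82.25th percentile). With 1 member per cluster of windows the hindbrain list lay inside the random lists (-0.03, 62.0th percentile) and the posterior Hox list stayed outside (-0.21, 0.13th percentile). Neurogenesis genes (0.14) and the histone family (0.06) were covered more in replicate 1, and the midbrain list did not stand apart (0.01, 49.5th percentile). The difference of the chemosensory receptors (-0.10) equals the centring value, because most members had no cover in either replicate. The genes with the largest ratios towards replicate 1 were Ube2e3 (12.5% against 5.73% of the window), Gm11146 (11.1% against 5.19%), Akt3 (11.2% against 5.35%), Sohlh2 (10.2% against 5.33%) and Slc29a4 (10.8% against 5.93%). Towards replicate 2 they were Hoxb6 (7.49% in replicate 1 against 10.6% in replicate 2), Lctl (7.36% against 10.4%), Bik (10.5% against 13.8%), Angptl8 (9.59% against 12.5%) and Fhad1 (7.95% against 10.3%). The forebrain difference was not outside the random lists with a -log10 q of at least 2 (34.1th percentile), with windows of 10 kb (71.7) or with windows of 100 kb (9.47), nor was that of neurogenesis genes with 10 kb (82.0) or of hindbrain genes with 100 kb (21.2). The difference of the histone family fell inside the random lists when GC content and CpG class were matched, and changed sign with 1 member per cluster (-0.05).

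Among the 20 chromosomes the X had by far the lowest cover, 0.850% of its sequenced bases against an autosome median of 5.89%. The ratio was 0.144 in the replicated list and 0.141 ± 0.0076 over the replicates. Chromosome 11 had the highest cover, 9.72%, followed by chromosome 19 with 7.59%, and the lowest autosome was chromosome 16 with 4.37%. The X carried 1791 of the 146616 replicated peaks.

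**Figure D5:**
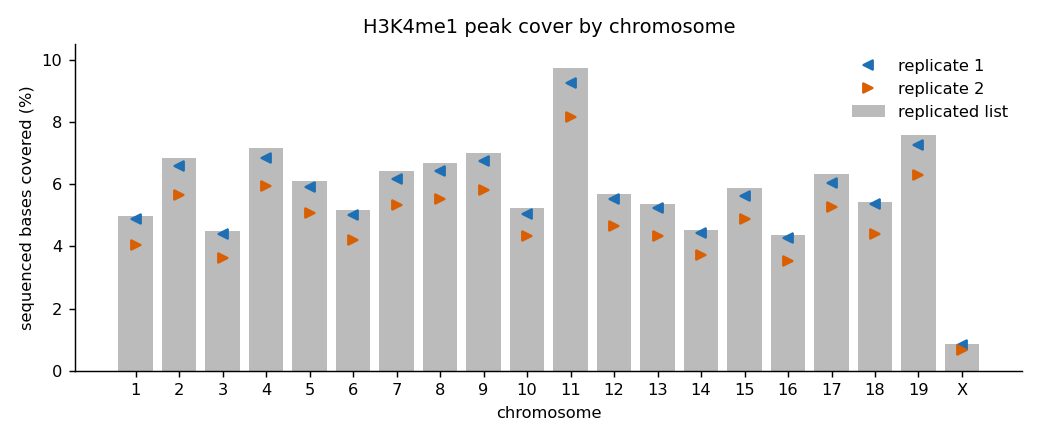
Percent of sequenced bases of each chromosome under H3K4me1 peaks, with bars for the replicated list and triangles for the 2 replicates. The X chromosome has 0.850% and the autosomes range from 4.37% on chromosome 16 to 9.72% on chromosome 11.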

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

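The tests of peak number, of cell makeup, of base composition, of coarser matching classes, of the 2 parts of the hindbrain list, of 1 member per cluster and of nearest-TSS windows were chosen only after the results they bear on were seen. In the joint list 4 peaks lay outside chromosomes 1 to 19 and X, 1 on the Y and 3 on unplaced sequences, a signal in data used in no comparison. Their signals ranged from 1.98 to 2.86, 0 of them were in the replicated list, and whether false calls alone would give as many was not tested.

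The X chromosome had 0.144 of the cover of the autosome median. Gene spacing and repeats were argued against as the whole cause: windows of 948 X-linked genes had 0.0905 of the cover of autosomal lists matched on gene length and density (0.54%, below all 1000 lists, the lowest of which had 5.01%), and within bases not marked as repeats the ratio was 0.183 (0.184 and 0.171 in the replicates). A lower signal of the X, as fewer X copies or an inactive X in mixed-sex pools could give, stays open. At 1, 2, 5 and 10 peaks per Mb the signal of the X was 0.489, 0.496, 0.495 and 0.478 of the autosome median. These ratios lay just under the range of 0.5 to 0.9 set before the test was run. The X had 16.74 joint peaks per Mb against an autosome median of 87.6, so an equal rank per Mb reached further down its list. Fewer marked sites on the X would lower these ratios as well, so the test cannot tell them from a lower signal. The design has no group by sex, so no biological explanation was tested, and X copy number and inactivation cannot be told apart in these pools.

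Relative to all genes, posterior Hox, cranial mesenchyme, hindbrain and forebrain lists were covered more in replicate 2 and neurogenesis genes more in replicate 1. Without this centring the forebrain median was higher in replicate 1 (12.4% against 11.7%) and that of cranial mesenchyme nearly equal (10.05% against 10.15%). The forebrain difference was inside the random lists with a -log10 q of at least 2 and with windows of 10 kb or 100 kb. The hindbrain value came from its 10 Hox members (-0.29 against 0.03 for the others on the log2 scale), so that it and the posterior Hox value rest in part on shared windows. Base composition and peak number were argued against as the whole cause, because 5 of the 5 lists stayed outside the central 95% of random lists matched on GC content and CpG class, and 5 of the 5 with the same number of peaks in both replicates, with the 2 lists of Hox windows not independent in either count. More cells from outside the neural tube in replicate 2 could contribute and stay open: of 5 lists of such tissues 1, cranial mesenchyme, lay below the central 95% (-0.15 on the log2 scale), while surface epithelium (-0.07), endothelial (-0.02), erythroid (-0.02) and microglia and myeloid genes (0.05) lay inside it. The number of further input files behind the peak lists, 2 for replicate 1 and 1 for replicate 2, cannot be told apart from a difference between the pools, because it changes with the replicate.

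Genes of microglia and myeloid cells, skeletal muscle, surface epithelium and cranial mesenchyme were called high in midbrain tissue. When only the part of each window nearest to the member's own TSS was counted, 1 of the 4 lists stayed above the central 95%, cranial mesenchyme (99.8th percentile), against 58.8 for microglia and myeloid genes, 86.8 for skeletal muscle and 95.5 for surface epithelium. With matching on GC content and CpG class 1 of the 4 lists stayed above it in the replicated list, again cranial mesenchyme, and the median of the random lists was 12.6% for microglia and myeloid genes, 12.1% for skeletal muscle and 11.4% for surface epithelium, against 6.44%, 5.37% and 5.67% with the same coarser classes of gene length and density alone, where 4 of the 4 lists kept the call. Cover nearer to other genes in GC-rich surroundings is a candidate explanation for these 3 lists, but which gene the cover belongs to was not tested. In the part nearest to the own TSS the median cover was 10.5% for surface epithelium, 7.64% for skeletal muscle and 5.50% for microglia and myeloid genes. Unmatched random lists ended the 4 calls as well. The midbrain list was at the 100th percentile in both tests, and with no other tissue in the design no biological explanation was tested.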

How the results depend on the processing

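The matching on GC content, the coarser matching classes, the nearest-TSS windows, the clusters of members and the peaks found in both replicates were chosen after the data were examined. Over 80 results, 601 of 691 alternative values kept their direction and call or, without a test, moved by no more than the replicate spread or, for counts of peaks, by at most 1.5-fold. The cause was not tested for the other values unless stated. With the peaks found in both replicates the replicated list covered 122 Mb, the promoter share was 11.4%, the intergenic share 36.4%, the X to autosome ratio 0.127, and the difference of flank minus centre was 0.133 points over all TSSs, opposite in sign, and -13.0 at CpG-poor TSSs. Requiring 50% of both peaks lowered the mean overlap of the replicates from 65.7% to 49.2%. The promoter and intergenic shares were 7.56% and 37.9% in the joint list, 4.45% and 39.2% with a promoter of 500 bp, 16.8% and 35.6% with 2.5 kb, and 18.5% and 35.2% with all transcript starts. Without other TSSs within 10 kb the flank difference was -5.61 points over all TSSs and 7.46 at CpG-rich TSSs.

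With a single replicate the promoter share ranged from 7.87% to 9.65%, the intergenic share from 36.6% to 37.1%, the flank difference from -1.96 (replicate 2) to 2.69 (replicate 1) over all TSSs and from -13.7 to -12.5 at CpG-poor TSSs, and the X ratio from 0.135 to 0.146. Of the joint peaks 18.7% to 40.3% of the weakest 10% by signal and 99.7% to 99.96% of the strongest were found in a single replicate. The overlap and the difference of the replicates need both and have no such value. The other overlap rules moved nothing in the replicated share, because replicated peaks are identical to joint peaks.

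The 10 lists called high were 6 with GC matching, 11 with the coarser length and density classes of that matching alone, and 7 to 12 in the other alternatives. The 2 lists called low were 1 with windows of 10 kb, 1 with a member per cluster and 1 with nearest-TSS windows, the keratin-associated family losing its call each time. With GC matching 2 were low again, but these were posterior Hox and liver genes. The midbrain, progenitor, neurogenesis, forebrain and signalling lists were called high in each of the 13 alternatives. The alternatives with each replicate alone could not end a call, because the main call already required both replicates. Their values are part of the counts per list and of the counts over all results. Of 299 values per list 29 lost and 13 gained a call, of 152 differences to the midbrain list 3 lost it, of 56 replicate differences 10 lost it and 1 reversed, and of 78 motif values 2 lost and 4 gained it. The reversed value was that of the histone family, -0.048 with 1 member per cluster. Depth is unknown for these lists, and whether the weak peaks of a replicate that are missing from the other are undetected there or are false calls was not tested. Of the peaks of replicate 1, 22.1% of the weakest 10% and 99.5% of the strongest were shared.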

Other observations

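The matching on GC content was chosen only after the data were examined, and the genes named here were chosen after their values were seen. Beyond the 5 longest domains, the domains of replicated peaks included 53458 bp over Igdcc3 and Igdcc4, 45089 bp in Ephb2 and 43952 bp over part of Pax7 (chromosome 4, 139795645 to 139839596). Others overlapped Ebf3 (37168 bp), Sema5b (36314 bp), Slit1 (33472 bp), Tcf7l2 (33429 bp) and Boc (33348 bp). In all, 135 domains were 20 kb or longer.

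In the synapse list 10 of 20 members lay above the upper quartile of all genes and 8 below the median. In the glia list 8 of 15 lay above the upper quartile, among them Olig1 (29.0%) and Olig2 (22.6%), genes of the oligodendrocyte lineage, and 4 lay below the median. The 15 glia genes form 14 clusters of windows, and with 1 member per cluster the list lay at the 96.9th percentile. Of the housekeeping genes 10 of 20 lay above the upper quartile and 3 below the median.

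Of the genes in the 20 lists 10 are X-linked, and 9 of these lay below the median of all genes, against 76 of 350 autosomal members. The exception was Sox3 with 7.13%. No replicated peak lay in the window of 41.5% of X-linked and 13.7% of autosomal protein-coding genes.

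The windows of posterior Hox genes had a median GC content of 48.9% against 44.3% for all genes, and 63.2% of their TSSs were CpG-rich. Their cover of 8.91% lay at the 0.01th percentile of lists matched on GC content and CpG class. The 19 genes form only 5 clusters of windows, and the percentile treats them as separate genes.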
